A study of Homo sapiens with 23 samples.

How the data were processed

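Poly(A) RNA was sequenced with paired ends from WM989 A6-G3, a clonal melanoma cell line, and from 7 drug-resistant clones of it. Samples were put in random order before RNA extraction and library preparation, per the labels' protocols. The series table held 1 value per gene and library for 35438 genes and 23 libraries, and every value column was matched to a sample by the library name in its label. The values were read here as TPM, transcript levels scaled to a fixed total per library, because each column summed to the same total. The table itself was named as counts. The submitters' processing notes name kallisto and hg19 with no version. The transcript annotation, the step from transcripts to genes and any filter of the authors are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown, no counting interval was given, and the spread between libraries was the measure of error.

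A count-based test had been fixed before the data were examined. Because the table was read as TPM, this test was replaced by limma on log2 values, chosen after the column totals were seen. TPM values were scaled between libraries by a trimmed mean of log ratios, computed here with 30% of log ratios and 5% of mean levels trimmed on each side over the 10822 genes with a TPM of at least 1 in every library. Scaling factors ran from 0.877 to 1.35. Genes with a TPM of at least 1 in at least 2 libraries were tested, 15657 in all. Values were taken as log2(scaled TPM + 1), and every log2 fold change stands on that scale, which understates the change of low genes. TPM levels in the text are scaled TPM. The scaling moved the result by more than a small amount: the median log2 fold change of all genes between the clones and untreated cells was -0.01 after scaling and 0.14 with the values as deposited. The median over genes of the difference between these fold changes was 0.16.

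All 23 libraries entered 1 limma fit (lmFit and eBayes with a trend, limma 3.58.1 in R 4.3.3) with 8 groups: untreated cells and clones 7 to 13. Each clone was contrasted with untreated cells, the unweighted mean of the 7 clones was contrasted with untreated cells, the 21 pairs of clones were contrasted, and equality of the 7 clones was tested with an F test of 6 degrees of freedom. A call required a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and an absolute log2 fold change of at least 1; the F test required a range of at least 1 between clones. A clone-specific gene was called in the same direction against each of the other 6 clones. For the drug arms, the mean log2 value of each clone was the unit, and limma compared 3 vemurafenib clones with 4 dabrafenib/trametinib clones. The error of the contrasts with untreated cells is the spread between libraries of the same clone. The labels call these biological replicates without saying what separated them, so their p-values may measure technical spread.

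There were 29 gene lists, written before the data were examined: melanocyte differentiation, drug-resistant WM989 state markers, neural crest-like state, MAPK pathway output, MAPK pathway genes, receptor tyrosine kinases and ligands, extracellular matrix and mesenchymal state, YAP and TEAD targets, AP-1 family, cell cycle, cell cycle inhibitors and p53 targets, interferon response, antigen presentation, inflammatory cytokines, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrial respiration, BCL2 family, ABC transporters, oxidative stress and ferroptosis, integrated stress response, lysosome and autophagy, ribosomal proteins, mitochondrially encoded genes, and markers of fibroblasts, keratinocytes, endothelium, immune cells and Schwann or neuronal cells. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, with camera's estimated correlation and limma's fry beside it. Members called were counted with p-values adjusted over all genes tested and adjusted over the list alone.

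Genes named in the report follow a rule written before the data were examined. It names a fixed panel (MITF, SOX10, TYR, MLANA, AXL, EGFR, NGFR, DUSP6, SPRY4, CCND1, MKI67 and BRAF), the 12 genes with the largest rise and the 12 with the largest fall among those called the same way in all 7 clones with a mean log2 value of at least 2, called genes of the arm comparison whose arms did not overlap and whose higher arm had a mean of at least 4 TPM, up to 4 higher and 2 lower clone-specific genes per clone at a mean of at least 4 TPM, and up to 4 members per gene list. Genes named outside it are said to be so. Some genes that the rule names are not reported here. Near-identical paralogs (HBG1 and HBG2, CCL3 and CCL3L3, CT45A5 and CT45A6, UGT1A10 and its family, SSX1, CSAG1, HLA genes, AKR1B10 and AKR1C3) are uncertain, since the estimation can divide reads between them. Gene annotation of GENCODE release 29 was used for chromosome membership, GC content and length in the closing section; it is of another build than hg19, and no coordinates are given.

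The procedure was tested on simulated values for the 15657 genes, drawn with each gene's mean and spread, with 50 genes changed per fold size. The changed genes were drawn from those with a mean log2 value over 2. Recovery was counted at an adjusted p under 0.05, without the fold minimum. It therefore overstates what the call would recover of genes changed 2-fold or less. For a clone against untreated cells, 32%, 74%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold were recovered. For the mean of the clones the shares were 62%, 90%, 98% and 100%, for the arms 8%, 46%, 88% and 90%, and for the F test with 1 clone changed 28%, 70%, 100% and 100%. In camera, 9 of 200 unchanged lists of simulated independent genes had an unadjusted p under 0.05. Real genes vary together: with permuted labels of the real libraries a median of 11 of the 29 lists was called, and 7 in other splits of the clones.

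Alternatives covered the scaling, the filter, the pseudocount, the fold minimum, a replicate term, array weights, the list test and leaving out each library in turn. The values as deposited, a pseudocount of 0.1, the filter at a TPM of 5, array weights and leaving out 2 doubted libraries were added after the data were seen. The doubted libraries were clone 8 replicate 3, with the highest share of ribosomal protein transcripts, and clone 10 replicate 1, with the fewest genes above 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.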

Results

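The libraries came from untreated WM989 A6-G3 cells, a line bottlenecked to a single cell from a BRAF-mutant human melanoma, and from 7 clones expanded from colonies of it that grew out under drug. The series asks how resistant cells from 1 parental line differ from each other. Clones 7, 8 and 9 were resistant to vemurafenib, an inhibitor of mutant BRAF, and were kept in 1 µM of it. Clones 10, 11, 12 and 13 were resistant to 250 nM dabrafenib, another BRAF inhibitor, with 2.5 nM trametinib, a MEK inhibitor, and were kept in both. Each group had 3 libraries, except clone 11 with 2. Untreated cells had no drug in the medium, so resistance and drug presence were confounded, as were drug arm and drug. Between 14415 and 24039 genes had a TPM above 0 per library, with the lowest number in clone 10 replicate 1 and 18671 or more in each of the others. The gene with the largest share of any library was MT-CO2, a mitochondrially encoded subunit of cytochrome c oxidase, at 33216 TPM as deposited in untreated replicate 1. Mitochondrially encoded transcripts made up 20.9% ± 0.31 (SD, n = 3) of untreated TPM and between 9.69% and 14.7% on average in the clones. Ribosomal protein transcripts made up 21.4% ± 1.03 (SD, n = 3) in untreated cells, 18.3% to 22.6% on average in clones 7, 8 and 9, and 10.9% to 14.2% in clones 10 to 13.

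The resistant clones were compared with the untreated parent to ask what they share. PMEL, SOX10, TYR, MLANA and MITF, genes of the melanocyte program, fell in all 7 clones. PMEL, the scaffold protein of pigment organelles, stood at 9864 ± 156 TPM (SD, n = 3) in untreated cells and at clone means between 10.1 and 254 TPM, a log2 fold change of -7.44 for the mean of the clones (SE 0.64, adjusted p = 8e-09). SOX10, a transcription factor of the melanocyte lineage, went from 469 ± 4.22 TPM to clone means between 0.427 and 11.7 TPM (log2 fold change -7.25, SE 0.53, adjusted p = 6.37e-10). TYR, the rate-limiting enzyme of melanin synthesis, fell by 6.70 and the melanosome antigen MLANA fell by 7.34 on the log2 scale. MITF, the regulator of this program, fell less, from 123 ± 11 TPM to clone means of 15.5 to 51.3 TPM (log2 fold change -1.95, SE 0.13, adjusted p = 1.26e-10). Of 21 tested genes of melanocyte differentiation, 18 fell, the same number adjusted over the list alone, and 17 fell in all 7 clones (camera adjusted p = 1.18e-13, adjusted p = 0.0609 with an estimated correlation). The other genes with the largest falls were S100B (-6.83), MIA (-5.38), APOD (-5.37), CAPN3 (-5.29), S100A1 (-5.15), GPM6B (-5.00), CEACAM1 (-4.59) and QPCT (-4.51), with adjusted p-values of 1.05e-08 or lower. In the neural crest-like list, 8 of 14 tested genes fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 0.00515, adjusted p = 0.224 with an estimated correlation). They included ERBB3, a receptor for neuregulin, at -6.61, RXRG at -5.17 and SOX5 at -3.05. NGFR, the nerve growth factor receptor of that list, had a log2 fold change of 0.48 (adjusted p = 0.0398), under the fold minimum, and was called higher in 1 clone.

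**Figure D1:**
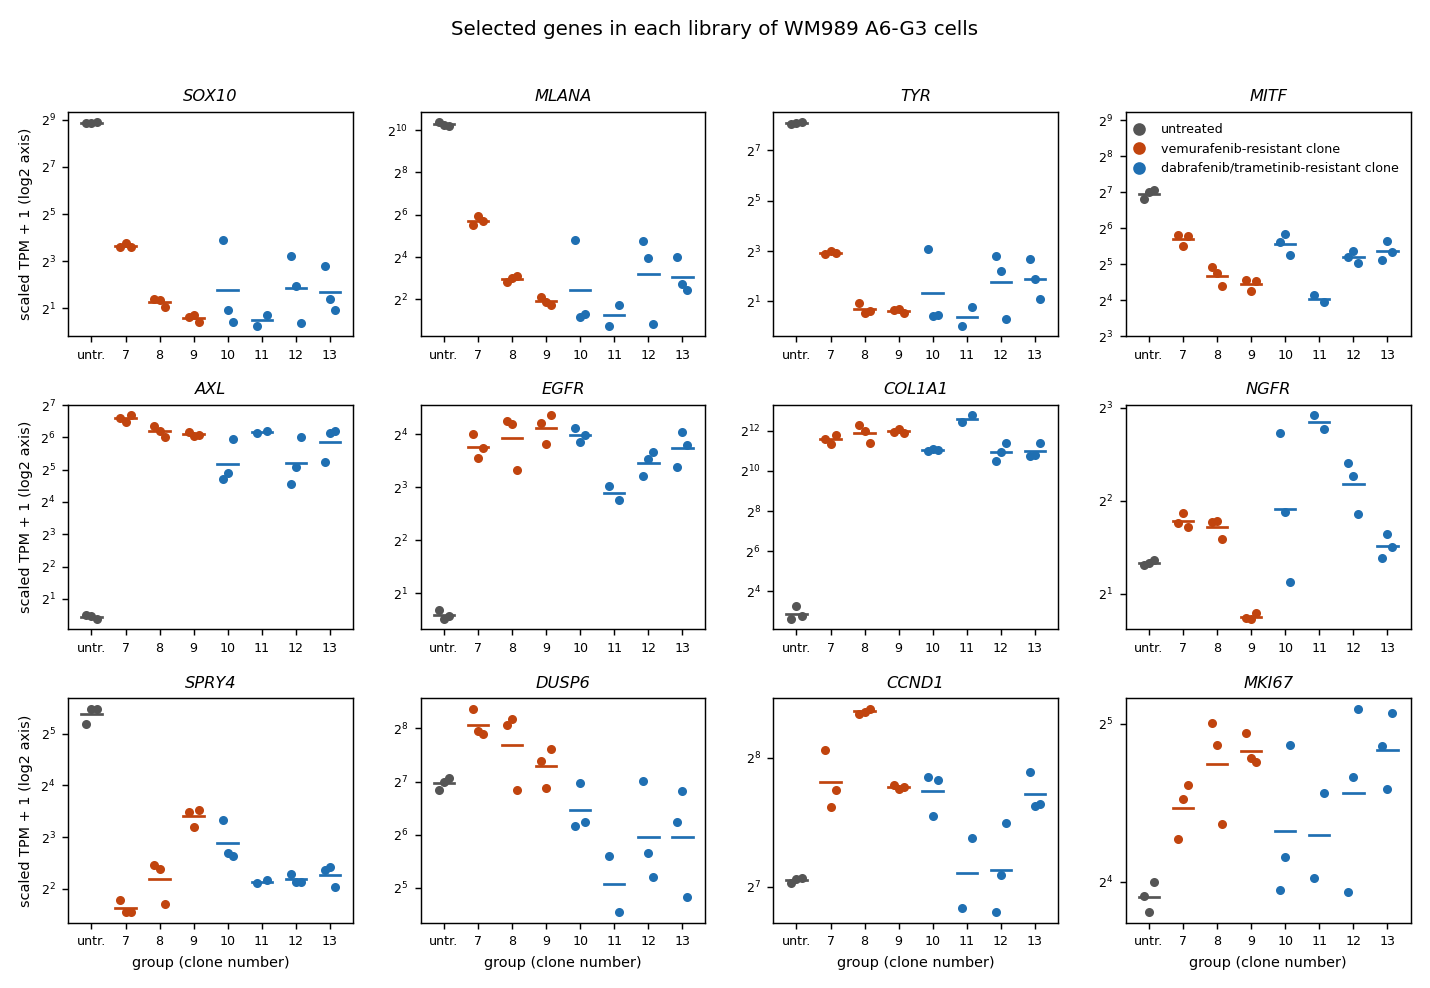
Scaled TPM plus 1 on a log2 axis in each library (points) of untreated cells and clones 7 to 13, with bars at the group means on the log2 scale. SOX10, MLANA and TYR stood far below the untreated libraries in every clone, while AXL, EGFR and COL1A1 stood above them.

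COL1A1, IGFBP7, AXL and EGFR rose in all 7 clones. COL1A1, a chain of type I collagen, went from 6.62 ± 1.93 TPM (SD, n = 3) to clone means between 2013 and 6187 TPM (log2 fold change 8.66, SE 0.18, adjusted p = 6.43e-18). IGFBP7, a secreted binding protein of the insulin-like growth factor axis, rose by 7.88, and the matrix proteoglycan BGN rose by 7.10. AXL, a receptor tyrosine kinase, rose from 0.364 ± 0.0698 TPM to clone means of 38.3 to 95.6 TPM (log2 fold change 5.46, SE 0.24, adjusted p = 2.32e-13), and EGFR, the epidermal growth factor receptor, to 6.51 to 16.7 TPM (log2 fold change 3.12, SE 0.17, adjusted p = 7.38e-12). Other genes with the largest rises were C1R (7.39), VCAM1 (7.09), CPA4 (6.96), BASP1 (6.90), SPOCK1 (6.79), CCL2 (6.77), ITGA11 (6.67) and COL5A1 (6.67), with adjusted p-values of 5.19e-13 or lower. Of 38 tested genes of the matrix and mesenchymal list, 32 rose and 0 fell, also adjusted over the list alone, and 23 rose in all 7 clones. The list call held with an estimated correlation (adjusted p = 1.03e-18, adjusted p = 0.00187 with an estimated correlation). LOXL2, an enzyme that cross-links collagen, rose by 6.34, and COL6A2 by 6.24. Of 41 tested receptor tyrosine kinases and ligands, 22 rose and 3 fell, the same adjusted over the list alone, with 11 higher and 2 lower in all 7 clones (adjusted p = 5.87e-07, adjusted p = 0.0226 with an estimated correlation). PDGFRB, a receptor for platelet-derived growth factor, rose by 6.00, VEGFC by 4.83, and the AXL ligand GAS6 by 3.71, while MERTK fell by 1.56. The list of drug-resistant WM989 state markers was written from knowledge of this line and is not independent evidence of its direction; 12 of 15 rose, also adjusted over the list alone, among them WNT5A at 5.86 (adjusted p = 2.22e-10, adjusted p = 0.0136 with an estimated correlation). Of 22 YAP and TEAD targets, 14 rose and 0 fell, also adjusted over the list alone (adjusted p = 4.17e-08, adjusted p = 0.0725 with an estimated correlation), including CCDC80 at 6.59, IGFBP3 at 5.36 and F3, tissue factor, at 5.31. Of 9 tested fibroblast markers, 8 rose, also adjusted over the list alone (adjusted p = 3.42e-06, adjusted p = 0.00228 with an estimated correlation). COL1A1 and COL3A1 belong to both this list and the matrix list, and FAP, a surface protease of activated fibroblasts, rose by 6.22. COL1A2, the partner chain of COL1A1 in type I collagen, rose by 4.71, and its clone means ran from 3.17 TPM in clone 10 to 366 TPM in clone 13.

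**Figure D2:**
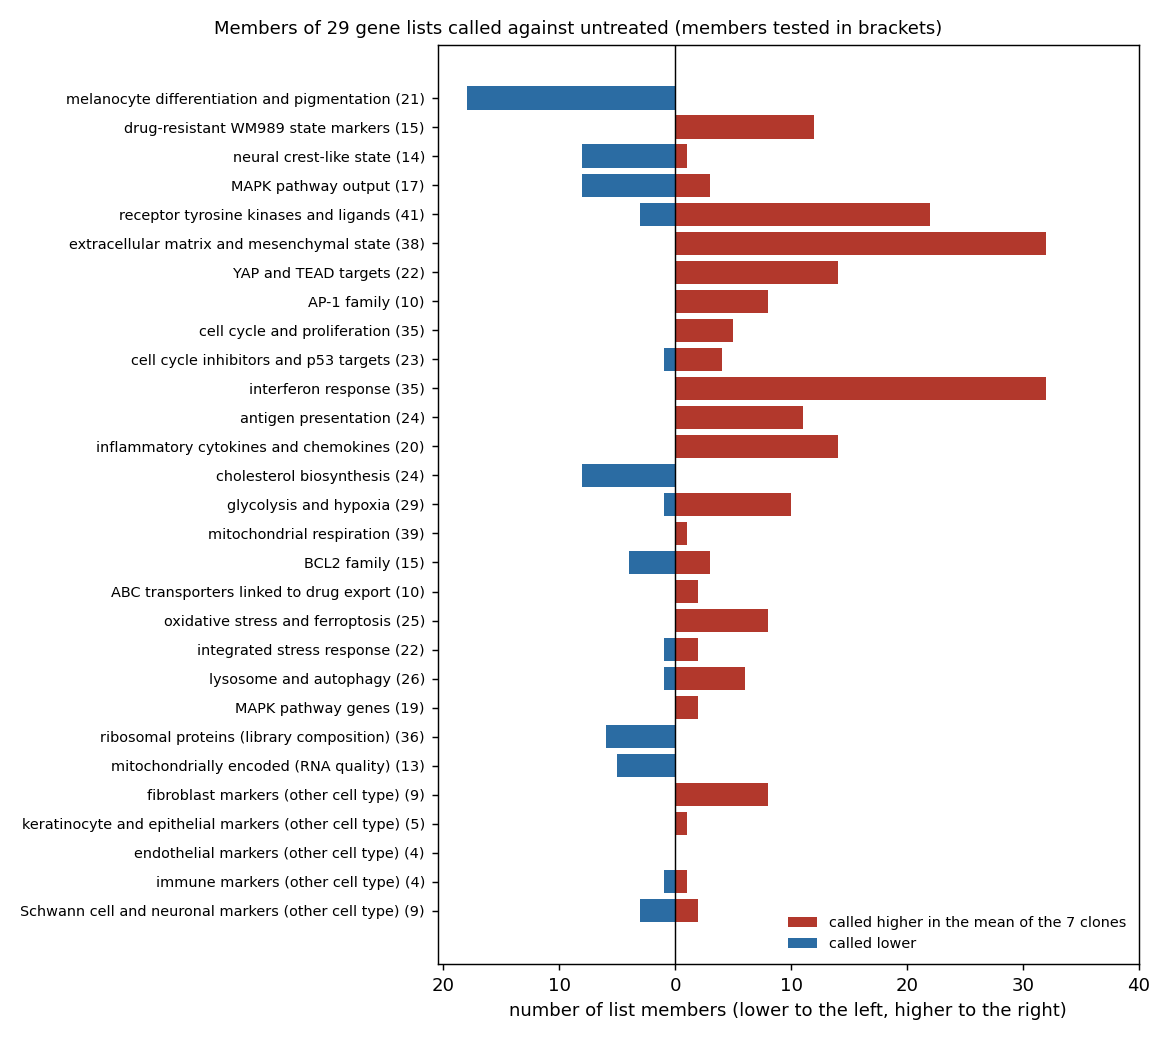
Bars give the number of members of each of 29 gene lists called higher (right) or lower (left) in the mean of the 7 clones against untreated cells, with the members tested in brackets. The interferon list had 32 of 35 higher and the melanocyte list 18 of 21 lower.

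SPRY4, SPRY2, DUSP4 and ETV4, targets of MAPK signaling, fell in all 7 clones, while EGR1, JUN and JUNB rose in all 7. SPRY4, an inhibitor induced by the pathway, fell to clone means of 2.09 to 9.63 TPM (log2 fold change -3.00, SE 0.15, adjusted p = 2.41e-12). SPRY2 fell by 3.51, the phosphatase DUSP4 by 3.43 and the transcription factor ETV4 by 4.15. EGR1, an immediate early transcription factor of the same list, rose by 4.18 (SE 0.45, adjusted p = 1.68e-07). DUSP6, the ERK phosphatase, had a log2 fold change of -0.32 (SE 0.37, adjusted p = 0.478), with clone means on both sides of the untreated 124 ± 9.99 TPM, from 34.8 to 271 TPM. Of 17 genes of MAPK output, 8 fell and 3 rose, also adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.142, adjusted p = 0.478 with an estimated correlation). In the AP-1 family, 8 of 10 genes rose, also adjusted over the list alone (adjusted p = 0.00431, adjusted p = 0.257 with an estimated correlation), with JUN at 4.25, JUNB at 3.20, FOSB at 2.83 and FOS at 2.00. FOSB and FOS were each called in 4 clones. In replicate 3 of clone 13, FOSB stood at 8.26 TPM and FOS at 52.9 TPM, below every untreated library. Of 19 MAPK pathway genes, 2 rose, MAP3K8 at 1.27 and SHOC2 at 1.06, also adjusted over the list alone (list adjusted p = 0.153); BRAF had a log2 fold change of -0.31 (adjusted p = 0.0625).

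Most genes of the interferon list rose in all 7 clones. IFITM1, an interferon-induced membrane protein, rose from 1.16 ± 0.3 TPM (SD, n = 3) to clone means of 51.5 to 383 TPM (log2 fold change 6.40, SE 0.15, adjusted p = 2.46e-17). IFI27 rose by 6.04, IFI44L by 6.02 and BST2, tetherin, by 5.98. The interferon list had 32 of 35 genes higher and 0 lower, also adjusted over the list alone, and 31 were higher in all 7 clones. Its medians ran from 2.39 in clone 7 to 3.32 in clone 8 (adjusted p = 1.96e-20, adjusted p = 0.0116 with an estimated correlation). In antigen presentation, 11 of 24 genes rose, also adjusted over the list alone, and 10 in all 7 clones (adjusted p = 1.41e-06, adjusted p = 0.0609 with an estimated correlation), with HLA-B at 4.86, the class I transactivator NLRC5 at 3.22, HLA-F at 3.05 and the immunoproteasome subunit PSMB9 at 2.83. Of 20 tested cytokines and chemokines, 14 rose and 0 fell, also adjusted over the list alone, and 9 rose in all 7 clones (adjusted p = 5.85e-08, adjusted p = 0.0116 with an estimated correlation), with CXCL12 at 6.62, IL6 at 6.34 and CSF1 at 5.01.

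MKI67, a marker of cycling cells, had a log2 fold change of 0.67 (SE 0.20, adjusted p = 0.00677) and CCND1, cyclin D1, of 0.61 (SE 0.12, adjusted p = 0.000271), both under the fold minimum. Of 35 cell cycle genes, 5 rose, also adjusted over the list alone, among them TK1 at 2.07, RRM2 at 1.86, KIF20A at 1.74 and CCNA2 at 1.33 (adjusted p = 0.000645, adjusted p = 0.561 with an estimated correlation). Of 23 cell cycle inhibitors and p53 targets, 4 rose and 1 fell, also adjusted over the list alone: FAS rose by 2.75, the CDK inhibitors CDKN1A by 2.62 and CDKN2C by 2.45, and PHLDA3 by 1.56, while BBC3, a proapoptotic BCL2 family member, had a log2 fold change of -1.42 (list adjusted p = 0.357; median -0.00683 and mean 0.342). In the BCL2 family, 4 of 15 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.706); BCL2A1 fell by 3.53 and HRK by 2.17, and BOK rose by 1.86. In cholesterol biosynthesis, 8 of 24 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00112, adjusted p = 0.466 with an estimated correlation), including the enzymes HSD17B7 at -2.25, TM7SF2 at -2.07, FDFT1 at -1.78 and HMGCS1 at -1.18. In glycolysis and hypoxia, 10 of 29 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00019, adjusted p = 0.224 with an estimated correlation), with ADM at 4.18, NDRG1 at 2.77 and the lactate transporter SLC16A3 at 2.11. In oxidative stress and ferroptosis, 8 of 25 rose, also adjusted over the list alone (adjusted p = 0.000711, adjusted p = 0.257 with an estimated correlation), with AKR1C3 at 3.31, TXNRD1 at 2.60 and NQO1 at 1.61.

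The remaining lists had few called members. In lysosome and autophagy 6 of 26 rose and 1 fell (adjusted p = 0.0538), with the V-ATPase subunit ATP6V0D2 at -3.32 and the protease CTSD at 1.66. In the integrated stress response 2 of 22 rose and 1 fell (adjusted p = 0.732), with STC2 at 3.46 and the amino acid transporter SLC7A5 at -1.18; its median of -0.232 and its test were negative and its mean of 0.0515 positive. Of 10 ABC transporters 2 rose, ABCG2 at 1.49 and ABCA1 at 1.07 (adjusted p = 0.405). Of 39 genes of mitochondrial respiration 1 rose, its regulator PPARGC1A at 1.48 (adjusted p = 0.357). Ribosomal protein genes fell in 6 of 36 members (adjusted p = 2.73e-07, adjusted p = 0.474 with an estimated correlation), with RPS3 at -1.14, and mitochondrially encoded genes in 5 of 13 (adjusted p = 2.74e-05, adjusted p = 0.153 with an estimated correlation), with MT-CYB at -1.64. In single clones 0 to 30 ribosomal protein genes were called lower, with medians from -1.27 in clone 10 to -0.0246 in clone 8. RPS3 was called lower in 4 clones. RPL5 was at -1.04 and lost its call without untreated replicate 1, at -0.99. Among markers of other cell types, 1 of 5 keratinocyte genes rose, KRT18 at 1.13 (adjusted p = 0.14). Of 4 endothelial genes limma called 0, with 3 at an unadjusted p under 0.05 (list adjusted p = 0.585). VWF, a clotting factor carrier, was at 0.95 and TIE1, a receptor, at -0.53, both under the fold minimum and called with a pseudocount of 0.1 (2.02 and -1.44). Of 4 immune markers 1 rose and 1 fell, CSF1R at 1.45 and FCER1G at -1.12 (adjusted p = 0.853). Of Schwann and neuronal markers, 2 of 9 rose and 3 fell, with SNAP25 at 4.55 (adjusted p = 0.706). Counts adjusted over the list alone were the same for each of these lists. With the values as deposited, the falls of RPS3 (-0.96), RPL5 (-0.86), FCER1G (-0.97) and SLC7A5 kept their direction and missed the fold minimum, and the lists of mitochondrial respiration (adjusted p = 0.0385) and of lysosome and autophagy (adjusted p = 0.047) passed. With the main scaling these lists had adjusted p = 0.865 and adjusted p = 0.563 with an estimated correlation.

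In numbers of genes, limma called 1700 higher and 1239 lower in the mean of the 7 clones against untreated cells. Against each clone the counts were 1719 higher and 1337 lower in clone 7, 1729 and 1454 in clone 8, 1795 and 1298 in clone 9, 1845 and 1649 in clone 10, 1832 and 1492 in clone 11, 1798 and 1256 in clone 12, and 1923 and 1308 in clone 13. Of 5954 genes called in at least 1 clone, 763 were higher and 654 lower in all 7, and 66 were called higher in 1 clone and lower in another. All clones shared the untreated libraries; with simulated unchanged groups sharing the same controls, 0 genes were called the same way in all 7. The correlation of fold changes across genes, which are not independent replicates, had a median of 0.872 over the 21 pairs of clones against 0.493 in the simulated groups. With the values as deposited, the balance moved toward higher genes in every clone: 1837 higher and 1165 lower in clone 7, 1760 and 1351 in clone 8, and 2041 and 1053 in clone 9. The move was larger in clones 10 to 13: 2515 higher and 1173 lower in clone 10, 2484 and 1036 in clone 11, 2171 and 967 in clone 12, and 2325 and 996 in clone 13.

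The clones were then compared with each other. By the F test 3958 genes differed among the 7 clones with a range of at least 1 on the log2 scale, which was 25.3% of the genes tested. POSTN, periostin, a matrix protein, stood at 200.5 ± 49.2 TPM (SD, n = 2) in clone 11 and at 2.68 TPM or less on average in the other clones, and clone 11 also had the lowest CXCL12, a chemokine, at 3.19 ± 0.463 TPM against 177 TPM or more elsewhere. VCAM1, a cell adhesion molecule, ranged from a clone mean of 10.1 TPM in clone 11 to 918 TPM in clone 10. Pairs of clones differed by 238 genes (clones 12 and 13) to 1902 genes (clones 8 and 10). The median was 769 genes for pairs of vemurafenib clones, 864.5 for pairs of dabrafenib/trametinib clones and 1075.5 for pairs of different arms; the difference between these medians was not tested.

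**Figure D3:**
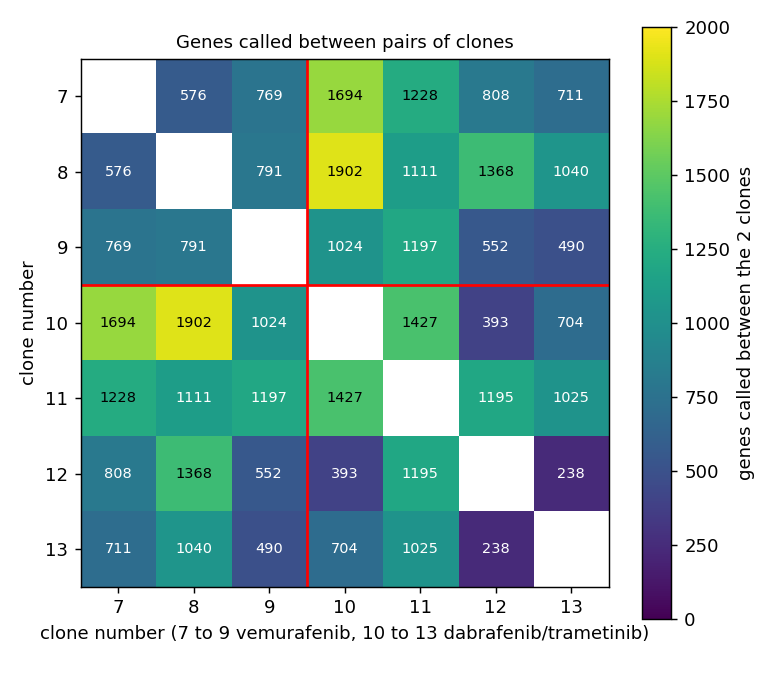
Number of genes called by limma between each pair of the 7 clones, with the clone number on both axes. Clones 12 and 13 differed by 238 genes and clones 8 and 10 by 1902.

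Clone-specific genes numbered 43 higher and 18 lower in clone 7, 31 and 17 in clone 8, 30 and 5 in clone 9, 44 and 54 in clone 10, 143 and 56 in clone 11, 5 and 0 in clone 12, and 24 and 0 in clone 13. Clone 7 had the highest CD36, a fatty acid transporter, at 213 ± 8.18 TPM (SD, n = 3) against 35.7 TPM or less on average in the other clones, and the highest fetal globin transcripts, HBG2 at 57.0 ± 19 TPM. MLANA was also highest there, at 52.2 ± 7.95 TPM against 13.9 TPM or less, and a test for untreated material mixed into clone 7 was undecided. Other values argued against such material as the sole source of melanocyte transcripts in clone 7. Clone 7 had the lowest MGST1, a glutathione transferase, at 1.61 TPM, and the lowest BST2. In clone 8, G0S2, an inhibitor of lipolysis, stood at 52.7 ± 12.2 TPM (SD, n = 3) against 0.661 TPM or less, TPRG1 and the chemokine CCL3 were highest, and QPRT, an enzyme of NAD synthesis, was lowest at 1.72 TPM, as was HTATIP2. Clone 9 had the highest TSPAN33 at 89.9 ± 10.7 TPM (SD, n = 3), complement factor I (CFI) at 95.1 ± 7.69 TPM, TGM2, a transglutaminase, at 263 ± 26.5 TPM and PRRX2, and the lowest SCG5 and CSAG1. In clone 10, ALDH1A1, an aldehyde dehydrogenase, stood at 128 ± 47.1 TPM (SD, n = 3) against 24.5 TPM or less, and ULBP3 and SLC27A6 were highest, while TNC, tenascin C, and the potassium channel KCNK2 were lowest. Clone 11 had the highest ACTC1, an actin, and TNS1, and the lowest TNFRSF11B, a decoy receptor. In clone 12 the tachykinin TAC3 stood at 114 ± 33.1 TPM (SD, n = 3), WISP2 at 178 ± 45.9 TPM, and MCF2L and ELSPBP1 were highest. In clone 13, SOST, a WNT inhibitor, stood at 46.9 ± 24.1 TPM (SD, n = 3) and the cancer-testis genes CT45A5 and CT45A6 and UGT1A10 were highest. Counts of clone-specific genes in both directions depended on the processing. With a pseudocount of 0.1 they were 97 in place of 61 in clone 7, 53 in place of 35 in clone 9, 197 in place of 98 in clone 10 and 8 in place of 5 in clone 12, and with treat at a fold of 1.5 they were 26, 20, 15, 21, 98, 0 and 10 in clones 7 to 13. The count of clone 10 was 215 in place of 98 without clone 10 replicate 3, and that of clone 12 was 18 in place of 5 without clone 12 replicate 3.

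The drug arms were compared with the clone as the unit, to ask whether resistance to vemurafenib and to dabrafenib/trametinib left different transcript levels. Limma called 2 genes, both higher in the 3 vemurafenib clones. NTN4, netrin 4, a secreted laminin-related protein, stood at 11.8 ± 3.51 TPM (SD over 3 clones) against 0.472 ± 0.556 TPM over 4 clones (log2 difference 3.16, SE 0.29, adjusted p = 0.0383). MT1X, a metallothionein, stood at 334 ± 36.6 TPM against 120 ± 11.8 TPM (log2 difference 1.46, SE 0.13, adjusted p = 0.0383). At an unadjusted p under 0.05 there were 2258 genes, against 189 to 2093 in other splits of the clones into 3 and 4. In 2246 genes, 14.3% of those tested, the clones of the arms did not overlap. By chance 5.71% is the average over all such splits. Genes vary together, so a single split can depart far from it, and overlap was not counted in the other splits. The count was 0 without clone 8 replicate 3, clone 9 replicate 1, clone 11 replicate 2 or clone 12 replicate 3, and without clone 7, 8, 9, 10, 12 or 13 as a whole, 4 without clone 7 replicate 2 or clone 10 replicate 1, 5 without clone 13 replicate 1, and 12 without clone 11. Of the 2 genes, MT1X alone lost its call without clone 10 replicate 2 (adjusted p = 0.059) and clone 13 replicate 2 (adjusted p = 0.0721). The number of genes called did not fall in these 2 cases, so another gene was called there. The count was also 0 with the values as deposited, with no filter, with a pseudocount of 0.1 and without both doubted libraries, and 432 when libraries were taken as the unit.

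Of 29 gene lists, 10 passed between the arms at the preset correlation and 0 with an estimated correlation, and 8 of 35 splits of the clones, the real one included, gave at least as many. No gene of them was called over all genes tested. DUSP6 stood at 217 ± 56 TPM in the vemurafenib clones and 66.8 ± 23.1 TPM in the dabrafenib/trametinib clones (log2 difference 1.82, SE 0.32, adjusted p = 0.154). EGR1 stood at 261 ± 12.1 against 154 ± 22.8 TPM (adjusted p = 0.154). The MAPK output list was higher in the vemurafenib arm by the list test, with 3 of 17 genes higher and 0 lower when adjusted over the list alone (adjusted p = 0.000482, adjusted p = 0.114 with an estimated correlation). FOSB stood at 218 ± 17.8 against 106 ± 8.98 TPM (log2 difference 1.60, SE 0.16, adjusted p = 0.0542), with single libraries of clones 10 to 13 between 8.26 and 252 TPM and replicate 3 lowest in each of these clones. The AP-1 list was higher with 3 of 10 genes when adjusted over the list alone (adjusted p = 0.000482, adjusted p = 0.114 with an estimated correlation). Ribosomal protein genes were higher as a list, 7 of 36 when adjusted over the list alone (adjusted p = 3.51e-29, adjusted p = 0.261 with an estimated correlation), with RPL7A at 1664 ± 205 against 671 ± 77 TPM (adjusted p = 0.0674). Keratinocyte markers were higher with 1 of 5 adjusted over the list alone (adjusted p = 0.0259, adjusted p = 0.261 with an estimated correlation), and cell cycle genes with 0 of 35 and 2 at an unadjusted p under 0.05 (adjusted p = 0.0259, adjusted p = 0.861 with an estimated correlation; adjusted p = 0.164 with the values as deposited).

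The cholesterol biosynthesis list was lower in the vemurafenib arm, with 7 of 24 genes lower when adjusted over the list alone (adjusted p = 2.93e-10, adjusted p = 0.315 with an estimated correlation). INSIG1, a sterol sensor, stood at 83.2 ± 18.5 against 258 ± 61.3 TPM (log2 difference -1.55, SE 0.22, adjusted p = 0.149), and lanosterol synthase (LSS) at 34.4 ± 3.24 against 82.4 ± 22.5 TPM (adjusted p = 0.154). Lysosome and autophagy genes were lower with 1 of 26 adjusted over the list alone (adjusted p = 0.000482, adjusted p = 0.503 with an estimated correlation), with LAMP1 at 124 ± 14.2 against 215 ± 23.9 TPM. Antigen presentation (0 of 24 adjusted over the list alone and 5 unadjusted, adjusted p = 0.000512, adjusted p = 0.261 with an estimated correlation), oxidative stress (1 of 25 lower, adjusted p = 0.000543, adjusted p = 0.618 with an estimated correlation) and ABC transporters (0 of 10 and 3 unadjusted, adjusted p = 0.000772, adjusted p = 0.114 with an estimated correlation) were also lower as lists. The other 19 lists did not pass, with adjusted p-values from 0.0575 to 0.987. Among these, the p53 list had a median of 0.19 and a mean of -0.0095, the cytokine list a median of 0.137 with a test in the other direction, and fibroblast markers a mean of -0.0788 that was 0.213 with the values as deposited. With those values 12 lists passed camera at the preset correlation. They included the matrix list (adjusted p = 0.0414), mitochondrially encoded genes (adjusted p = 0.0414) and Schwann or neuronal markers (adjusted p = 0.0208). Adjusted over the list alone, 1 YAP and TEAD target was higher and 1 lower, and 1 neural crest-like and 1 Schwann or neuronal marker were higher.

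**Figure D4:**
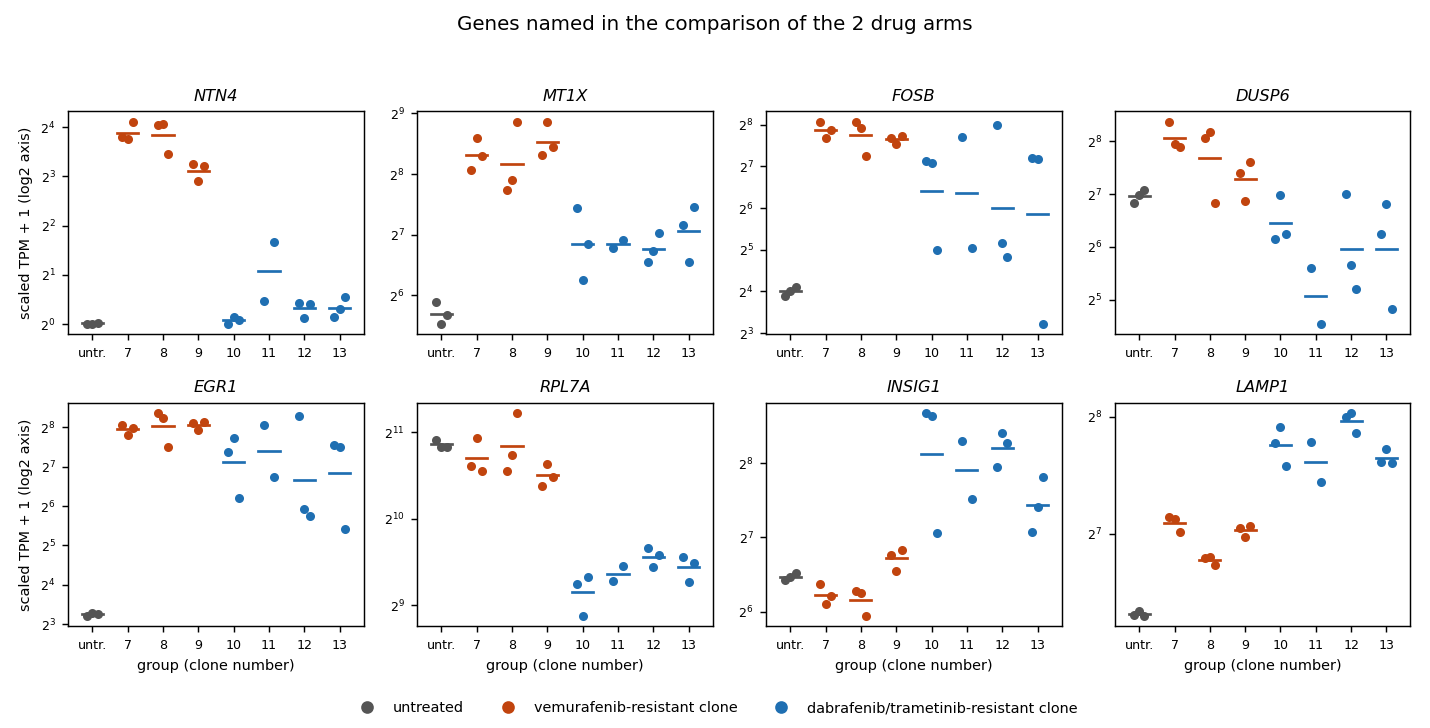
Scaled TPM plus 1 on a log2 axis in each library (points) of untreated cells, the vemurafenib clones 7 to 9 and the dabrafenib/trametinib clones 10 to 13, with bars at the group means on the log2 scale, for genes named in the comparison of the arms. NTN4 and MT1X passed the test and the other genes did not.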

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

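The tests of melanocyte transcripts and of fibroblasts were chosen only after the results were seen, and the tests of the chromosome shifts were written beforehand. Values were tested for a clone far from the others among the 4 dabrafenib/trametinib clones, in 120 genes and lists, and chance picks out about 1 in 20 such groups. The test picked out 9 of the 120, so it did not exclude chance for any of them. Clone 11 stood apart for SOX10 (log2 fold change against untreated -8.38, others -7.17 to -7.03), COL1A1 (9.68, others 8.03 to 8.12), VCAM1 (2.89, others 8.46 to 9.36) and CDKN1C (0.56, others 1.77 to 2). Clone 11 had no replicate 1, which held the highest SOX10 in clones 10, 12 and 13 (3.01%, 1.78% and 1.27% of untreated). In replicates 2 and 3 SOX10 stood at 0.0416% and 0.141% in clone 11 and at 0.0618% to 0.61% in those clones. These ranges overlapped, so SOX10 does not set clone 11 apart without replicate 1. Clone 10 stood apart for CEACAM1 (-4.03, others -4.73 to -4.64), HLA-DPA1 (-0.68, others 0.76 to 0.85), PTPRC (0.3, others -0.22 to -0.15) and the median of the neural crest-like list (-0.87, others -1.11 to -1.09). Clone 10 includes the doubted replicate 1. In clone 10, SOX10 stood at 3.01% of untreated in replicate 1 and at 0.196% and 0.0762% in replicates 2 and 3. The values by which clone 10 stood apart were not recomputed without replicate 1. Clone 12 stood apart for KRT18 (0.15, others 0.68 to 0.78).

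A difference between the drug arms passed its test for NTN4 (3.16) and MT1X (1.46). By the list test at the preset correlation, the mean difference was 0.5 for MAPK pathway output, 0.57 for the AP-1 family, 0.15 for cell cycle genes, 0.86 for ribosomal proteins and 0.53 for keratinocyte markers. It was -0.32 for antigen presentation, -0.69 for cholesterol biosynthesis, -0.57 for ABC transporters, -0.52 for oxidative stress and -0.39 for lysosome and autophagy. With an estimated correlation 0 of these 10 lists passed. Every clone of one arm moved against untreated cells in the opposite direction to every clone of the other for DUSP6 (difference between arms 1.82, adjusted p = 0.154), RRM2B (-0.39, adjusted p = 0.281), LSS (-1.15, adjusted p = 0.154) and NRAS (-0.36, adjusted p = 0.31). The opposite directions themselves were not tested, and the test between arms did not pass for these genes. Among all 35 splits of the 7 clones into 3 and 4, 5 gave at least the 2 genes of the real arms, the highest other split gave 110, and 8 gave at least the 10 lists, with 14 as the highest other and a median of 7. Chance was therefore not excluded for either. At an unadjusted p under 0.05 the real arms gave 2258 genes, the most of the 35 splits, with 2093 in the highest other.

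Clones 7, 8, 9, 10, 12 and 13 each gave the most genes against untreated cells in 1 of 10 splits, the real one (3093, 3178, 3121, 3287, 3085 and 3267 genes), and 0 in the highest other; 10 splits are too few to exclude chance. A random assignment of single libraries to groups was excluded for the mean of the clones (1 of 100 draws, 2939 genes, highest other 2822 in a draw that kept all 3 untreated libraries). The same held for genes shared by all 7 clones (2 of 100, 1417, highest other 1536 in that same draw). It also held for differences among clones (1 of 100, 3958, highest other 980) and for clone-specific genes (1 of 100, 470, highest other 38). Libraries of 1 clone may differ by technical spread alone, so dividing them between groups was bound to lower such counts. Of the other draws of group labels, 98 moved an untreated library and 1 kept all 3. These draws therefore hardly test sharing among the clones. Random assignment was not excluded for the number of lists called in the mean of the clones (10 of 100, 17 lists, highest other 19, median 11). Clone 11, with 2 libraries, was not tested in this way.

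Genes of whole chromosomes stood together: 17 of 154 pairs of clone and chromosome had a median log2 deviation of at least 0.2 from the median of the other 6 clones, with the largest falls on chromosome 4 in clone 8 (-0.452, 86.8% of genes lower) and chromosome 13 in clone 9 (-0.422, 93.1% lower). Chromosome 9 went with the drug arm, from 0.196 to 0.294 in the vemurafenib clones and from -0.258 to -0.08 in the others, which was not tested. Clones 7, 11 and 13 were under the minimum shift on this chromosome, and in clone 11 only 1 of 2 libraries was lower. GC content or gene length bias was argued against by 15 pairs still called after correction. All 17 pairs had the same sign in every library of the clone, as predicted if no single atypical library was the cause. The pairs were picked on the mean of these same libraries, and most pairs not called also had 1 sign in every library. Only signs were compared, so a single library that carried most of a shift was not excluded. All 17 had the same sign in all 3 classes of expression level, as predicted for copy number differences between the clones. The pairs were picked on the median of these same genes, and most pairs not called also had 1 sign in all classes. The check therefore cannot tell copy number from other causes. Copy number differences are a hypothesis only, as DNA was not analysed here.

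Melanocyte transcripts were followed in 9 silenced genes of the list. Each had at least 30 TPM in untreated cells and under 0.5% of that in some library of another clone. Over all 21 tested genes of the list the median log2 fold change in clone 7 was -4.15. Medians of the 9 genes stood at 1.97% to 2.62% of the untreated level in clone 7. In replicates 1 to 3 they stood at 2.78%, 0.174% and 0.147% in clone 10, 2.22%, 1.35% and 0.0975% in clone 12, and 1.33%, 0.473% and 0.359% in clone 13. Replicate 1 was thus highest in clones 10, 12 and 13, as it was for PRAME, and what the replicate numbers share was not tested. Untreated RNA, cells or reads mixed in could raise them, and other silenced genes should then rise by a like share. The percentage of them under 0.5 of the melanocyte median was 48.7%, 41% and 35.9% in replicates 1 to 3 of clone 7. It was 54.8% in clone 10 replicate 1 and 43.6% in clone 12 replicate 1, and the test was undecided in each case. Mixing alone would leave no gene under the mixed share. In replicates 1 to 3 of clone 7, DCT, EDNRB and RAB38 stood at 0.521% to 0.955%. These values argue against mixing as the sole source of the clone 7 medians. A smaller share in clone 7, and the single libraries of clones 10 and 12, stay undecided. No biological explanation was tested.

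Of 9 tested fibroblast markers 7 rose in all 7 clones, and fibroblasts in the cultures could do this. MFAP5, another of the 9, was called lower in 3 clones. COL1A2 reached at most 3.65% of COL1A1 in clones 7 to 12. This argues against fibroblasts as the main source of COL1A1 there, as these make both chains. The ratio cannot exclude a smaller share of fibroblasts that brought COL1A2 (114 TPM in clone 9 and 209 TPM in clone 11) or other markers. PRAME, a melanoma antigen, stood at 32% to 57.6% of its untreated level in the clone libraries, which a share of other cells could also bring. Other cells, a smaller share of fibroblasts included, were thus left open. COL1A2 reached 19.5% in clone 13, where the test was undecided.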

How the results depend on the processing

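The tests under the values as deposited, a pseudocount of 0.1, a TPM of at least 5 in at least 3 libraries, array weights and without both doubted libraries were chosen only after the data were seen. A second count-based test fixed beforehand was not run, since the values were read as TPM. Over 47 settings 344 results were recomputed. Of 380 alternative counts of genes or lists in the main comparisons, 324 stayed within a factor of 1.5 of the reported count. Among named genes and lists, 0 called results reversed. Among named genes and lists not called, 9 alternative values moved under other settings and 18 on leaving out a library or clone, including fibroblast markers and cytokines between arms as deposited. The arm comparison (2 genes) gave 0 as deposited, with no filter, with a pseudocount of 0.1 and without both doubted libraries, 432 at the library level, and 0 to 12 on leaving out a library or clone. Clone-specific genes of clone 12 (5) were 3 with a TPM of at least 5 in at least 3 libraries, 8 with a pseudocount of 0.1 and 8 without both doubted libraries. With no minimum fold, by construction, clones 7 to 13 gave 7416, 7542, 7132, 7912, 6792, 7278 and 7580 genes, their mean 8855, all 7 together 3236, the F test 8480, and clone-specific genes 223, 323, 146, 275, 564, 23 and 56. With treat at a fold of 1.5, clone-specific genes of clones 7 to 13 were 26, 20, 15, 21, 98, 0 and 10. With a pseudocount of 0.1 they were 97 in clone 7, 53 in clone 9 and 197 in clone 10. Lists called in the mean of the clones (17) were 6 with an estimated correlation and 26 with fry, and between arms (10) 0 and 5. On leaving out 1 library, clone-specific genes ran from 98 to 215 in clone 10 and from 4 to 18 in clone 12. The cause was not tested. A replicate block gave 2945 genes in the mean of the clones and 431 between arms at the library level. Replicate numbers were not taken as paired: of 77 pairs with the same number 28 correlated above 0.1, from -0.623 to 0.418, though 11 of 15 did among the dabrafenib/trametinib clones, from -0.0706. Depth is unknown; the lowest percentile of TPM, a relative floor, was 0.222 in clone 10 replicate 1, 31.5 times the median library, and 4.33 times in clone 7 replicate 1.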

Other observations

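Genes of these paragraphs and their tests were chosen only after the values were seen. ZEB1, a repressor of epithelial genes, rose by 1.81 (SE 0.14, adjusted p = 2.2e-09) and TCF4 by 2.15 in the mean of the clones, while LEF1, a mediator of WNT signaling, had a log2 fold change of -2.33 and TFAP2A, a lineage transcription factor, of -2.30. SNAI2 rose by 1.08 and was called in 5 clones, and TWIST1 by 1.04, called in 4. TGFB1 rose by 2.27, TGFBI by 2.91 and SMAD3 by 1.73. Of complement genes looked at, C1S rose by 5.64 and CFB by 2.32, both called in 7 clones, SERPING1 by 2.17, called in 6, and C3 by 1.13, called in 3.

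Surface molecules moved unevenly. PDCD1LG2, a ligand of PD-1, rose by 2.68 and B2M, the light chain of class I molecules, by 2.15, while CD274 was at 0.59 (adjusted p = 0.0723). The matrix proteases MMP1 and MMP2 rose by 3.99 and 5.93, PLAU had a log2 fold change of -2.64, and its receptor PLAUR rose by 1.94. ITGA5, a fibronectin receptor subunit, rose by 4.82, with a mean of 2006 TPM in clone 11 and 85.5 TPM in clone 10. TERT, the catalytic subunit of telomerase, was deposited at 1.37 to 2.38 TPM in untreated libraries and at 0.024 TPM or less in every clone library.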
